A study of Mus musculus with 14 samples.

How the data were processed

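RNA of primary hepatocytes and of total liver from male C57Bl6 mice, fed CSAA or CDAA for 2 weeks, was hybridized to Clariom S mouse arrays, 1 array per sample. Per the labels, hepatocytes came from collagenase perfusion and total liver from the caudal lobe, the tissues were extracted with different RNA kits, and RNA was labelled with the WT PLUS reagents. The deposited values are log2 intensities that the authors made by RMA, that is background correction, quantile normalization and summary per probe set. The version of RMA is not stated. Array medians over all probe sets lay close together within a tissue, at 4.56 to 4.71 in hepatocytes and 6.07 to 6.24 in total liver. Medians over the tested probe sets alone were parted by diet. In hepatocytes they were 4.68 to 4.76 on CSAA and 4.85 to 4.89 on CDAA. In total liver they were 5.85 to 5.91 on CSAA and 6.00 to 6.06 on CDAA. The tissues differed far more than the diets, so the authors look to have normalized them as 2 sets. Levels were therefore not compared between the tissues, but for 1 test of other cells' markers added after the data were seen: the planned comparison of total liver with hepatocytes on CSAA was not run, nor were its alternatives.

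The table holds 28846 probe sets. Of these 6640 control probe sets (introns, exons, ERCC, AFFX) were left out and 22206 were tested, without a filter on dim probe sets. Gene symbols came from the annotation given with the series, and 19572 of the tested probe sets had 1 symbol, 0 had several and 2634 had none. There were 19505 symbols, 55 of them with more than 1 probe set, for which the brightest stood for the gene in the lists. Of 628 list members 60 found no named probe set. No coordinates are given, as no genome build is named with the values.

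Samples were grouped by tissue and diet as titled: 3 arrays per diet for hepatocytes and 4 for total liver. One linear model with a mean per group was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3, with 10 residual and 5.11 prior degrees of freedom. Contrasts were CDAA minus CSAA in each tissue and the difference of the 2, total liver minus hepatocytes. The moderated test was two-sided, with Benjamini-Hochberg adjustment over all tested probe sets per contrast and a threshold of 0.05. Overlap of calls was set against the product of the shares, and log2 fold changes were correlated across genes.

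The design, the 36 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists are named for their theme, and not every member belongs to it in the strict sense. Such members include Cd36 and Fabp4 among lipid droplet genes, Vcam1 among cytokines and chemokines, and Mylip among cholesterol export genes. Camera, with its preset correlation of 0.01, tested the 35 lists with at least 5 measured members, adjusted over the lists. The list of erythroid and platelet genes had fewer and was not tested. Camera with an estimated correlation and fry were run beside it. The value with an estimated correlation is given beside a list mainly where the list no longer passed. For lists that still passed it was far larger than the preset value, and its range is given per comparison. Named genes were, per diet contrast, the 8 highest and 8 lowest log2 fold changes among genes past the threshold whose groups did not overlap, without predicted genes, receptor segments or olfactory genes. For the difference between tissues they were the 5 highest and 5 lowest past the threshold. To these were added up to 4 members per list with the smallest p, and a fixed set of lipid, fibrosis, macrophage and hepatocyte genes whatever their p. A further list of 19 female-biased genes, 18 of them measured, was written later, before its test but after the values of 3 members had been seen.

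The alternatives were limma with trend and robust moderation, the 2 compared groups alone in the fit, leaving out the dimmest 30% of probe sets, joint quantile normalization, centring on array medians, array weights, the replicate number as a block, leaving out each array, and the mean over a gene's probe sets. Added after the data were seen were centring within a tissue on the median of the less bright hepatocyte function genes (3 genes under a level of 16 in every group), centring on all of them, and a spread estimated per tissue for the difference between tissues. Also after the data were seen, a group was taken as not above background where all its arrays lay under the 95th percentile of the intron control probe sets of the same array, and a bound was then taken from that percentile. Replicate numbers did not pair the arrays: residuals of equal numbers correlated at 0.35, -0.21 and 0.26 in hepatocytes and at -0.13 to 0.02 in total liver.

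The code was tested on simulated data with the CSAA means, spreads and array numbers of this series, over 22206 genes. With 1 spread for both tissues, 2.56% to 7.58% of calls were false with 200 changed genes and 3.98% to 4.63% with 4000. With each tissue's own moderated spread, the fit over all arrays gave false shares of 52.5% in hepatocytes, 2.55% in total liver and 18.5% for the difference with 200 changed genes, and 17.2%, 1.26% and 8.23% with 4000. Each tissue's own arrays gave 3.51% and 7.41% with 200, and 3.95% and 3.93% with 4000. The shared spread was fixed in advance and kept, and hepatocyte counts are therefore given under both fits. In that simulation with 4000 changed genes, the fit over all arrays recovered 73.2% of log2 changes of 1 and 98.9% of 2 in hepatocytes, 87.2% and 99.4% in total liver, and 43.4% and 94.7% for the difference.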

Results

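Gene expression was measured on 14 Clariom S mouse arrays, in adult male wild-type C57Bl6 mice fed for 2 weeks either CSAA, the control diet, or CDAA, a choline-deficient diet with added cholesterol, glucose and fructose. Primary hepatocytes, obtained by collagenase perfusion, gave 3 arrays on CSAA and 3 on CDAA. Total liver, taken from the caudal lobe after perfusion with saline, gave 4 arrays per diet. Values are on the log2 scale, and a difference of 1 is a doubling. The median over all probe sets lay between 4.56 and 4.71 in the hepatocyte arrays and between 6.07 and 6.24 in the total liver arrays. Arrays of 1 group correlated across probe sets at 0.978 to 0.983 (hepatocytes, CSAA), 0.952 to 0.982 (hepatocytes, CDAA), 0.990 to 0.993 (total liver, CSAA) and 0.990 to 0.995 (total liver, CDAA). The hepatocyte arrays deviated more from their group means, by 0.363 to 0.594 (root mean square), than the total liver arrays, by 0.229 to 0.320. The number of arrays limits the precision. The 95th percentile of the intron control probe sets lay between 6.84 and 8.01 in the hepatocyte arrays and between 9.96 and 10.23 in the total liver arrays, a bound on background chosen after the data were seen. Where all arrays of a group lie under it, the fitted value is followed by the change that is left with that group at the percentile ("bound"), or by "no bound" where none is left, in the same way for differences between tissues. Below, a gene's value in parentheses is its log2 fold change, CDAA minus CSAA, ± SE.

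**Figure D1:**
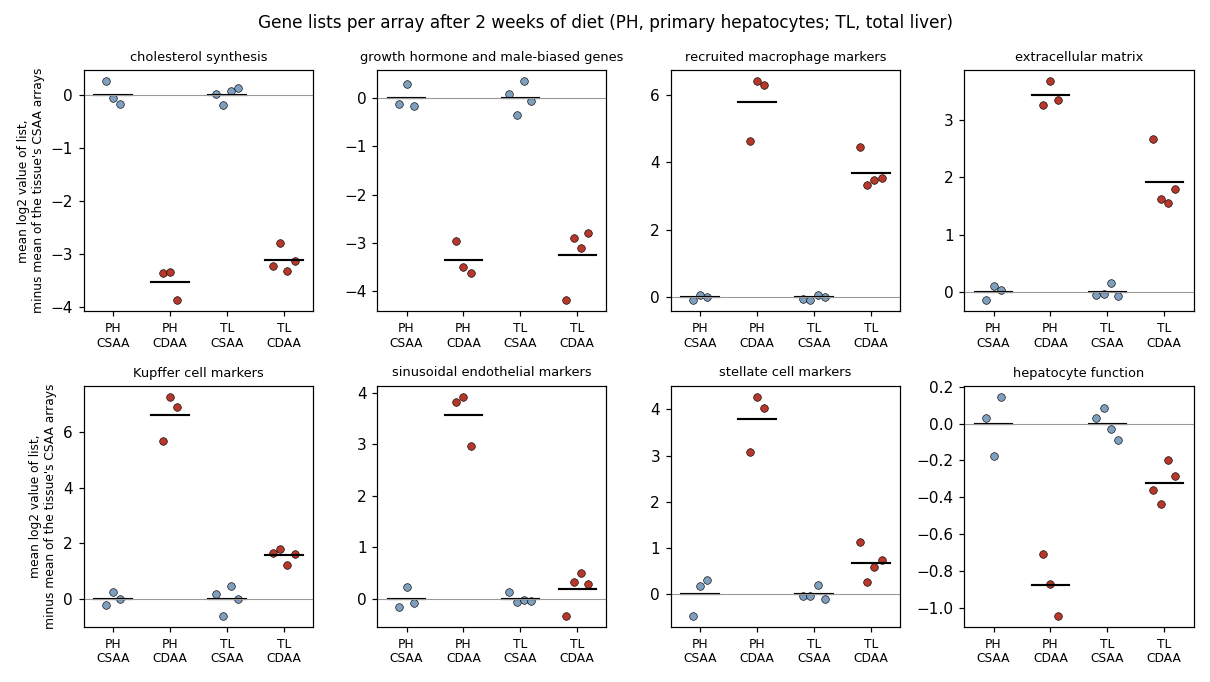
Each point is 1 array: the mean log2 value of a gene list, minus the mean of the CSAA arrays of the same tissue (primary hepatocytes, PH, 3 arrays per diet; total liver, TL, 4 per diet). Bars are group means, and the vertical scales differ between panels. Kupffer cell markers stood 5.67 to 7.28 above the CSAA mean in the CDAA hepatocyte arrays and 1.22 to 1.78 above it in the CDAA total liver arrays.

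The first comparison asked which genes differed between the diets in total liver (n = 4 arrays per diet). On CDAA, nearly every measured gene of cholesterol synthesis was lower, and so were the male-biased genes of the liver. Markers of recruited macrophages, chemokines, matrix genes, oxidative stress genes, lysosomal genes and genes of cell division were higher. Of the genes of cell division, 19 of 20 lay under the background percentile on each diet. Mmp12, a macrophage elastase (probe set TC0900000046.mm.2), rose from 6.39 ± 0.33 (SD) on CSAA to 16.54 ± 0.33 on CDAA, a fitted difference of 10.15 ± 0.38 (at least 6.46 above background). Hsd3b5, a steroid dehydrogenase expressed mainly in male liver (probe set TC0300002554.mm.2), fell from 17.25 ± 0.06 to 7.28 ± 1.41, a fitted difference of -9.97 ± 0.51 (a fall of at least 7.22 to background). Other genes with large fitted changes were Ly6d (7.39 ± 0.29, bound 2.42) and Lilr4b (5.75 ± 0.34, bound 1.04), which rose, and Adgrf1 (-6.24 ± 0.28, bound -1.81) and Cyp4a12b (-4.44 ± 0.48), which fell.

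In total liver, 18 of 19 measured genes of cholesterol synthesis fell (19 adjusted over the list alone, camera, adjusted p = 2.53e-31 and, with an estimated correlation, adjusted p = 0.0013), with a median of -3.001. Among them were Sqle (-5.80 ± 0.31, bound -1.53), Idi1 (-5.01 ± 0.37), Fdps (-4.37 ± 0.36, bound -1.80), Nsdhl (-4.23 ± 0.24) and Hmgcs1 (-3.24 ± 0.42); Sqle encodes squalene epoxidase. Of the 13 genes of cholesterol export and esterification, 2 rose (6 adjusted over the list alone, camera, adjusted p = 0.00039 and, with an estimated correlation, adjusted p = 0.169). These were the transporter gene Abcg1 (2.08 ± 0.36, no bound) and the phospholipid transfer protein gene Pltp (2.40 ± 0.56). The sterol transporter gene Abcg5 had 1.51 ± 0.59 and did not pass. Bile acid genes moved both ways, with 2 of 21 up and 6 down (5 and 7 adjusted over the list alone), and the list did not pass as a whole (camera, adjusted p = 0.0535). Higher were Cyp7a1 (2.18 ± 0.66), the rate-limiting enzyme of bile acid synthesis, and the exporter subunit Slc51b (1.90 ± 0.39, no bound). Lower were Cyp8b1 (-2.97 ± 0.63), the sterol 12-alpha-hydroxylase, Cyp7b1 (-3.84 ± 0.30), an enzyme of the alternative pathway, and the uptake transporter Slco1a1 (-4.49 ± 0.78).

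Lipogenic genes were lower as a list in total liver, with 5 of 19 falling (6 adjusted over the list alone, camera, adjusted p = 0.000933 and, with an estimated correlation, adjusted p = 0.449). Members that fell included Acly (-2.54 ± 0.43), Acss2 (-2.41 ± 0.38), Lpin1 (-2.09 ± 0.48) and Thrsp (-3.36 ± 0.80), whereas Fasn (-1.92 ± 0.82) and Scd1 (0.54 ± 0.45) did not pass. Lipid droplet genes were higher as a list, with 4 of 18 rising (6 up and 1 down adjusted over the list alone, camera, adjusted p = 0.00602 and, with an estimated correlation, adjusted p = 0.111). These were Cidec (5.18 ± 0.34, bound 0.89), Cd36 (4.52 ± 0.35, bound 3.76), Fabp4 (1.78 ± 0.52, bound 0.33) and Hsd17b13 (0.74 ± 0.19). Plin2, which coats lipid droplets, had 0.03 ± 0.28 and did not pass. Of 21 fatty acid oxidation genes Acot2 (3.96 ± 0.52) rose and Acaa2 (-0.66 ± 0.17) fell. The list counted 1 up and 1 down (2 and 1 adjusted over the list alone, camera, adjusted p = 0.0382 and, with an estimated correlation, adjusted p = 0.58). Acot2 has a near-identical paralogue, and whether its probe set tells the copies apart was not checked. Of the 22 genes of choline and one-carbon metabolism, 1 fell (0 adjusted over the list alone, but 8 down and 1 up with the spread of the total liver arrays alone), the glycine methyltransferase gene Gnmt (-1.01 ± 0.30), and the list did not pass (camera, adjusted p = 0.0658). Pemt, which makes phosphatidylcholine by methylation, had -0.32 ± 0.18 and Bhmt had -0.13 ± 0.31, neither past the threshold.

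Macrophage genes rose in total liver. Of 16 recruited macrophage markers 15 rose and 1 fell (the same numbers adjusted over the list alone, camera, adjusted p = 1.53e-22), with a median of 3.27. Among them were Mmp12, Gpnmb (8.67 ± 0.38, bound 3.49), Lgals3 (5.62 ± 0.53, bound 0.56), Chil3 (4.42 ± 0.43, no bound) and Trem2 (4.05 ± 0.55, no bound), a lipid receptor of macrophages. The list mean stood above the CSAA mean by 4.46 in CDAA replicate 1 against 3.33 to 3.54 in the other CDAA arrays. The marker that fell was Fabp5 (-2.94 ± 0.47, bound -1.46), a fatty acid binding protein gene named here after its value was seen. Kupffer cell markers had 7 of 12 up (8 up and 1 down adjusted over the list alone, camera, adjusted p = 2.5e-08 and, with an estimated correlation, adjusted p = 0.0939) and a median of 1.69. Among them were Cd5l (3.20 ± 0.35), Marco (3.11 ± 0.37, no bound) and Csf1r (1.92 ± 0.28). The Kupffer marker Clec4f (1.06 ± 0.53) did not pass. MHC class II genes had 6 of 8 up (8 adjusted over the list alone, camera, adjusted p = 1.58e-09 and, with an estimated correlation, adjusted p = 0.0763). They included H2-Ab1 (3.12 ± 0.51, bound 2.65) and H2-Aa (2.93 ± 0.50). Cytokine and chemokine genes had 18 of 24 up (21 adjusted over the list alone, camera, adjusted p = 1.34e-19). They included Ccl3 (3.67 ± 0.25, no bound), Vcam1 (3.58 ± 0.27, bound 1.27) and Cxcl10 (3.53 ± 0.43, no bound). Interferon response genes had 14 of 20 up (16 adjusted over the list alone, camera, adjusted p = 2.2e-13 and, with an estimated correlation, adjusted p = 0.0557). They included Mx1 (2.10 ± 0.21, no bound) and Gbp3 (2.17 ± 0.35, bound 0.03). Acute phase genes had 6 of 19 up (8 adjusted over the list alone, camera, adjusted p = 2.57e-06 and, with an estimated correlation, adjusted p = 0.175). Among them were Lcn2 (7.46 ± 0.59), the gene of a siderophore-binding protein, and Saa3 (3.09 ± 0.32, bound 2.45). Wholly under the intron control percentile lay 13 of 16 recruited macrophage markers on CSAA and 8 on CDAA. The same held for 22 and 13 of 24 cytokine and 15 and 12 of 20 interferon response genes. For Kupffer markers these numbers were 6 and 2 of 12, and for MHC class II 6 and 3 of 8. The sizes of these list changes thus rest partly on values not above background.

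Markers of other cell types of the liver were tested as well. Of 12 neutrophil markers 4 rose (4 adjusted over the list alone, camera, adjusted p = 0.015 and, with an estimated correlation, adjusted p = 0.175). Among them were Csf3r (2.30 ± 0.36, no bound) and S100a8 (2.31 ± 0.70, no bound), and the list mean stood above the CSAA mean by 1.28 in CDAA replicate 1 against 0.48 to 0.60 in the other CDAA arrays. T and NK cell markers had 3 of 15 up and 1 down (4 and 1 adjusted over the list alone, camera, adjusted p = 0.0509). The NK receptor gene Ncr1 (1.32 ± 0.23, no bound) rose and Cd4 (-0.81 ± 0.23, no bound) fell. None of 8 B cell markers (camera, adjusted p = 0.916) and none of 11 cholangiocyte markers (camera, adjusted p = 0.0382 and, with an estimated correlation, adjusted p = 0.449) passed by limma over all genes or adjusted over the list alone. In total liver 8 of 8 B cell, 12 of 12 neutrophil and 15 of 15 T and NK cell markers lay wholly under the intron control percentile on each diet. Of cholangiocyte markers 11 of 11 did on CSAA and 10 of 11 on CDAA. Members of these lists that did not pass are therefore weak evidence that such cells did not change. Lying under the percentile did not prevent calls, as the 4 neutrophil markers that rose show. Cholangiocyte markers stood, against the CSAA mean, at 1.07 in CDAA replicate 1 against 0.02 to 0.36 in the other CDAA arrays. Of 17 sinusoidal endothelial markers 1 rose (1 adjusted over the list alone, camera, adjusted p = 0.206), Lyve1 (2.58 ± 0.34, bound 0.64). Against the CSAA mean the list mean stood at -0.33 in CDAA replicate 1 against 0.30 to 0.49 in the other CDAA arrays. The median of 0.12 turned to -0.03 after joint quantile normalization and to -0.02 after centring on array medians. It rose to 0.97, with 8 of 17 up, after centring on the 3 less bright hepatocyte function genes, a scaling chosen after the data were seen. On each diet 8 of the 17 lay wholly under the intron control percentile. Stellate cell markers had 2 of 12 up (3 adjusted over the list alone, camera, adjusted p = 0.00388 and, with an estimated correlation, adjusted p = 0.357). These were Des (1.14 ± 0.26, no bound) and Pdgfrb (1.57 ± 0.39, no bound). Extracellular matrix genes had 20 of 23 up (22 adjusted over the list alone, camera, adjusted p = 6.48e-21). They included the collagen genes Col3a1 (3.96 ± 0.33, bound 1.64) and Col1a1 (2.33 ± 0.33, no bound), the collagenase gene Mmp13 (5.14 ± 0.53, no bound) and the protease inhibitor gene Timp1 (2.90 ± 0.41, no bound). Their mean stood above the CSAA mean by 2.68 in CDAA replicate 1 against 1.56 to 1.80 in the other CDAA arrays. Of the 23 matrix genes, 20 lay wholly under the intron control percentile on CSAA and 16 on CDAA. Of the 12 stellate cell markers 8 and 7 did, so the sizes of both changes rest partly on values not above background.

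Genes of stress, lysosomes and cell division were tested in total liver. Oxidative stress genes had 10 of 18 up (12 adjusted over the list alone, camera, adjusted p = 3.78e-15). They included the metallothionein gene Mt2 (6.93 ± 0.80), Gsta2 (6.78 ± 0.44), the sulfiredoxin gene Srxn1 (5.996 ± 0.54, bound 3.50) and the heme oxygenase gene Hmox1 (3.44 ± 0.33, bound 3.15). Lysosomal genes had 8 of 15 up (12 adjusted over the list alone, camera, adjusted p = 4.02e-11). Among them were Atp6v0d2 (5.26 ± 0.51, bound 1.84) and Hexa (2.07 ± 0.23). Proliferation genes had 15 of 20 up (18 adjusted over the list alone, camera, adjusted p = 1.68e-16). Among them were Mki67 (3.47 ± 0.41, no bound), Ccnb2 (2.89 ± 0.29, no bound) and Cdk1 (2.62 ± 0.27, no bound). On each diet 19 of the 20 lay wholly under the intron control percentile, so the sizes of these changes rest on values not above background. Targets of p53 had 7 of 13 up (9 adjusted over the list alone, camera, adjusted p = 2.54e-08). Among them were the cell cycle inhibitor Cdkn1a (4.89 ± 0.76, bound 1.88) and Eda2r (3.14 ± 0.33, no bound). Genes of the unfolded protein response moved both ways, 3 up and 2 down of 22 (4 and 2 adjusted over the list alone, camera, adjusted p = 0.439). Of its members Trib3 (3.31 ± 0.47, bound 1.14) and Ddit3 (2.26 ± 0.44, bound 0.86) rose and the chaperone gene Sdf2l1 (-1.76 ± 0.37) fell. Immediate early genes had 3 up and 1 down of 17 (the same numbers adjusted over the list alone, camera, adjusted p = 0.206), with a median of -0.002 and a mean of 0.55.

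Among hepatocyte genes of total liver, 9 of 14 growth hormone and male-biased genes fell (12 adjusted over the list alone, camera, adjusted p = 9.7e-13), with a median of -2.24. The list mean, against the CSAA mean, was -4.18 in CDAA replicate 1 against -3.09 to -2.79 in the other CDAA arrays. Besides Hsd3b5 they included the fatty acid elongase gene Elovl3 (-7.59 ± 1.02), Cyp4a12a (-5.14 ± 0.51) and Cyp7b1; Cyp4a12a has a near-identical paralogue. Hepatocyte transcription factors had 2 of 16 down (5 adjusted over the list alone, camera, adjusted p = 0.00286 and, with an estimated correlation, adjusted p = 0.375). These were Mlxipl (-1.17 ± 0.29) and Onecut1 (-3.96 ± 1.10). Hnf4a had -0.52 ± 0.40 without passing. Hepatocyte function genes had 1 of 21 down (the same number adjusted over the list alone, camera, adjusted p = 0.0417 and, with an estimated correlation, adjusted p = 0.357), Agxt (-1.82 ± 0.34). Albumin, Alb, had -0.00 ± 0.14, but lay at 19.30 on both diets, at the top of the array values, where a change can hardly show. The medians of these last 2 lists, -0.69 and -0.27, turned to 0.16 and 0.59 when arrays were centred on the 3 less bright hepatocyte function genes, a scaling chosen after the data were seen. Cytochrome P450 and conjugation genes had 6 up and 5 down of 20 (6 and 8 adjusted over the list alone, camera, adjusted p = 0.842), with a median of -0.30 and a mean of 0.25. In this list Cyp2b10 (3.64 ± 0.51, no bound) and Cyp2a5 (4.52 ± 0.59) rose and Cyp2c54 (-2.63 ± 0.44) fell; Cyp2a5 has a near-identical paralogue. Sugar metabolism genes had 2 up and 4 down of 19 (3 and 5 adjusted over the list alone, camera, adjusted p = 0.45). The pyruvate kinase gene Pkm (3.28 ± 0.26, bound 1.37) was higher and the glucose-6-phosphatase gene G6pc (-2.31 ± 0.55) was lower. Pericentral genes (1 of 12 down), periportal genes (2 up and 1 down of 10), circadian clock genes (0 of 16) and oxidative phosphorylation genes (0 of 17) did not pass as lists, with adjusted p = 0.272, 0.96, 0.76 and 0.0566. Adjusted over the list alone, the periportal list had 3 up and 1 down, and the other 3 had the same numbers as over all genes. The periportal median was -0.24, although camera gave a direction upward.

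Over all 22206 probe sets tested in total liver, 2279 passed, 1494 higher and 785 lower on CDAA, of which 1210 and 412 differed by a log2 value of at least 1. Every CDAA array lay beyond every CSAA array in 5569 probe sets, 25.1% of those tested, against 2.86% by chance. By camera, 22 of 35 gene lists shifted, 17 up and 5 down, of which 9 held with an estimated correlation. Those 9 had adjusted p of 0.0013 to 0.0172 by camera with the estimated correlation, far above their preset values. The count was 4613 with the spread taken from the total liver arrays alone, 4992 with array weights, and 1510 without CDAA replicate 1. With the spread from the total liver arrays alone Abcg5, Clec4f, Fasn, Hnf4a and Scd1 passed, with adjusted p = 0.0324, 0.0093, 0.0027, 0.0395 and 0.0472. List counts that moved by at least 3 with that spread were those of cholesterol export and esterification (7 up), bile acid synthesis and transport (6 up and 9 down), lipogenesis (1 up and 12 down), fatty acid oxidation (6 up and 1 down), sugar metabolism (4 up and 7 down) and hepatocyte transcription factors (6 down). So were those of hepatocyte function (5 down), cytochrome P450 and conjugation (6 up and 8 down), cytokines and chemokines (21 up), interferon response (17 up), stellate cell markers (6 up and 1 down) and Kupffer cell markers (10 up), as well as p53 targets (10 up), growth hormone and male-biased genes (12 down), oxidative phosphorylation (3 down), lysosome (12 up) and choline and one-carbon metabolism (1 up and 8 down). Targets of p53 passing upward were 4 without CDAA replicate 1, CDAA replicate 2 or CSAA replicate 2. Fatty acid oxidation genes passing upward were 4 without CSAA replicate 1. Hepatocyte transcription factors passing downward were 0 without CSAA replicate 4 or CDAA replicate 1, and lipogenic genes 3 without CDAA replicate 1. List means of cytokines and chemokines, against the CSAA mean, were 2.68 in CDAA replicate 1 against 1.68 to 1.97 in the other CDAA arrays. Those of MHC class II were 3.10 in CDAA replicate 1 against 1.90 to 2.33 in the other CDAA arrays, and those of immediate early genes 1.16 in CDAA replicate 1 against 0.15 to 0.66 in the other CDAA arrays. Of 81 genes given here as changed in total liver, 29 had 1 group and 19 both groups wholly under the 95th percentile of the intron controls. The higher share was 65.6%, against 43.4% after centring on array medians, which moved the median of all genes from -0.09 to -0.23.

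The second comparison asked the same of primary hepatocytes (n = 3 arrays per diet). Here too genes of cholesterol synthesis and male-biased genes were lower on CDAA. Markers of Kupffer cells, recruited macrophages, sinusoidal endothelial cells and stellate cells were all far higher in the CDAA preparations. Mmp12 went from 3.92 ± 0.42 (SD) to 18.32 ± 1.18, a fitted difference of 14.39 ± 0.44 (at least 10.58 above background), and Hsd3b5 from 17.63 ± 0.50 to 7.27 ± 0.60, a difference of -10.36 ± 0.58. Further large changes were those of Lilrb4a (10.30 ± 0.48, bound 7.18), Rgs1 (9.78 ± 0.81, bound 6.52) and Fabp7 (9.57 ± 0.44, bound 6.67), upward, and the glycogen-targeting subunit gene Ppp1r3c (-5.33 ± 1.11), downward. Because the hepatocyte arrays spread more than the total liver arrays and all arrays shared 1 spread per gene, each count below is followed by the count with the spread taken from the hepatocyte arrays alone ("own spread"). By own spread Ppp1r3c did not pass, with adjusted p = 0.0654. The SE printed for hepatocyte genes rest on the shared spread and understate the uncertainty of many of them. By own spread the SE was 0.57 for Mmp12 and 0.63 for Lilrb4a, though smaller for some genes, such as Hsd3b5 with 0.39.

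Of 12 Kupffer cell markers, 12 rose in the hepatocyte preparations (12 by own spread, 12 adjusted over the list alone, camera, adjusted p = 1.01e-21), with a median of 6.94. Among them were Cd5l (10.23 ± 0.41, bound 9.30), Clec4f (8.36 ± 0.61, bound 6.18) and C1qa (7.14 ± 0.43, bound 6.22). Recruited macrophage markers had 15 of 16 up (15 by own spread, 15 adjusted over the list alone, camera, adjusted p = 4.52e-21 and, with an estimated correlation, adjusted p = 0.0157). Among them were Gpnmb (10.22 ± 0.44, bound 6.16), Lyz2 (10.26 ± 0.54, bound 9.10) and Trem2 (7.76 ± 0.64, bound 3.50). Sinusoidal endothelial markers had 16 of 17 up (15 by own spread, 17 adjusted over the list alone, camera, adjusted p = 2.98e-19), with a median of 3.56. Among them were Lyve1 (6.19 ± 0.39, bound 3.74) and Cdh5 (4.55 ± 0.42, bound 2.71). Stellate cell markers had 11 of 12 up (10 by own spread, 12 adjusted over the list alone, camera, adjusted p = 4.47e-15), with a median of 3.69. Among them were Dcn (7.18 ± 0.59) and Sod3 (6.14 ± 0.45, bound 4.16). MHC class II genes had 7 of 8 up (7 by own spread, 7 adjusted over the list alone, camera, adjusted p = 1.16e-12), with a median of 7.13. In the markers of 4 further cell types the numbers adjusted over the list alone were the same as over all genes. Neutrophil markers had 4 of 12 up (4 by own spread, camera, adjusted p = 0.036 and, with an estimated correlation, adjusted p = 0.214). T and NK cell markers had 4 of 15 up (3 by own spread, camera, adjusted p = 0.00974 and, with an estimated correlation, adjusted p = 0.264). B cell markers had 2 of 8 up (1 by own spread, camera, adjusted p = 0.0582), and cholangiocyte markers 2 of 11 (1 by own spread, camera, adjusted p = 0.322). In hepatocytes 8 of 8 B cell and 10 of 11 cholangiocyte markers lay wholly under the intron control percentile on each diet. On CDAA so did 14 of 15 T and NK cell and 10 of 12 neutrophil markers. The neutrophil median of 0.12 turned to -0.04 after centring on array medians, and the cholangiocyte median of -0.03 lay below 0 while the mean was 0.29.

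Genes of cytokines, matrix, stress and division rose in the same hepatocyte arrays in which the Kupffer markers rose by a median of 6.94. Cytokine and chemokine genes had 23 of 24 up (22 by own spread, 23 adjusted over the list alone, camera, adjusted p = 1.23e-26). Among them were Ccl3 (8.59 ± 0.29, bound 4.70), Vcam1 (8.59 ± 0.32, bound 4.65) and Cxcl2 (7.14 ± 0.37, bound 2.66). Extracellular matrix genes had 20 of 23 up (18 by own spread, 21 up and 1 down adjusted over the list alone, camera, adjusted p = 5.41e-20). Among them were Sparc (9.04 ± 0.43, bound 8.44), Col3a1 (6.70 ± 0.38, bound 3.99), Col1a1 (2.79 ± 0.38, no bound) and Timp1 (4.53 ± 0.47, no bound). Wholly under the intron control percentile lay 22 of 24 cytokine and 21 of 23 matrix genes on CSAA, and 4 and 9 on CDAA. Interferon response genes had 12 of 20 up (5 by own spread, 14 adjusted over the list alone, camera, adjusted p = 8.4e-09 and, with an estimated correlation, adjusted p = 0.114). One of them was Ifit2 (3.22 ± 0.34, no bound). Acute phase genes had 7 up and 3 down of 19 (7 and 0 by own spread, 8 and 3 adjusted over the list alone, camera, adjusted p = 0.00495 and, with an estimated correlation, adjusted p = 0.344). Among those that rose were Lcn2 (11.44 ± 0.69, bound 9.45) and Il1rn (6.90 ± 0.44, bound 3.58). Oxidative stress genes had 10 of 18 up (8 by own spread, 11 adjusted over the list alone, camera, adjusted p = 6.28e-07 and, with an estimated correlation, adjusted p = 0.113). Among them were Hmox1 (6.72 ± 0.38), Gsta2 (6.52 ± 0.50) and Nqo1 (3.90 ± 0.43, bound 1.27). Lysosomal genes had 11 of 15 up (8 by own spread, 12 adjusted over the list alone, camera, adjusted p = 1.06e-10). Among them were Hexa (3.84 ± 0.26) and Ctsb (2.66 ± 0.21). Proliferation genes had 17 of 20 up (13 by own spread, 19 adjusted over the list alone, camera, adjusted p = 7.54e-16). Among them were Cdk1 (3.57 ± 0.31, no bound) and Ccnb2 (3.78 ± 0.34, bound 0.81). Of the 20, 18 lay wholly under the intron control percentile on CSAA and 11 on CDAA. Targets of p53 had 4 of 13 up (1 by own spread, 4 adjusted over the list alone, camera, adjusted p = 0.00151 and, with an estimated correlation, adjusted p = 0.134). One of them was Cdkn1a (5.64 ± 0.88). Immediate early genes, which the isolation of cells can raise, had 6 of 17 up (4 by own spread, 6 adjusted over the list alone, camera, adjusted p = 2.87e-05 and, with an estimated correlation, adjusted p = 0.255). Among them were Klf6 (6.02 ± 0.57, bound 3.39) and Ier3 (5.17 ± 0.66, bound 1.81). Their mean stood 1.15 to 3.71 above the CSAA mean in the CDAA arrays and -0.98 to 1.25 from it in the CSAA arrays, so the groups overlapped.

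Lipid genes fell or rose in the hepatocyte preparations beside these markers of other cells, of which endothelial markers rose by a median of 3.56 and stellate markers by 3.69. All 19 measured genes of cholesterol synthesis fell (18 by own spread, 19 adjusted over the list alone, camera, adjusted p = 1.48e-22), with a median of -3.40. Among them were Sqle (-5.77 ± 0.36, bound -2.94), Idi1 (-5.30 ± 0.43), Fdps (-5.19 ± 0.42, bound -3.92) and Hmgcs1 (-4.15 ± 0.48). Lipogenic genes had 12 of 19 down (4 by own spread, 16 adjusted over the list alone, camera, adjusted p = 1.01e-07 and, with an estimated correlation, adjusted p = 0.189). Among them were Acly (-3.99 ± 0.50), Mlxipl (-3.25 ± 0.33) and Fasn (-4.03 ± 0.94), whereas Scd1 had -0.08 ± 0.52. Lipid droplet genes had 4 of 18 up (4 by own spread, 4 adjusted over the list alone, camera, adjusted p = 0.0409 and, with an estimated correlation, adjusted p = 0.214). These were Cd36 (8.86 ± 0.40, bound 7.26), Fabp4 (5.53 ± 0.60, bound 3.65), Cidec (3.49 ± 0.39, bound 1.24) and Hilpda (3.15 ± 0.45, bound 1.30). The list had a median of -0.07 and a mean of 1.07, while Plin2 had -0.42 ± 0.33 and did not pass. Cholesterol export genes had 5 of 13 up (4 by own spread, 5 up and 2 down adjusted over the list alone, camera, adjusted p = 0.0137 and, with an estimated correlation, adjusted p = 0.264). Among them were Pltp (5.35 ± 0.65), Mylip (4.87 ± 0.47, bound 2.38) and Abcg1 (3.77 ± 0.42, bound 0.34), and Abcg5 had 0.74 ± 0.68 without passing. Bile acid genes had 2 up and 8 down of 21 (1 and 5 by own spread, 2 and 10 adjusted over the list alone, camera, adjusted p = 0.00151 and, with an estimated correlation, adjusted p = 0.217). Lower were Cyp7b1 (-5.08 ± 0.35) and Cyp8b1 (-3.87 ± 0.72) and higher Slc51b (3.14 ± 0.45, no bound) and Cyp7a1 (2.30 ± 0.76). By own spread Cyp7a1 and Fasn did not pass, with adjusted p = 0.141 and 0.105. Genes of choline and one-carbon metabolism had 9 of 22 down (2 by own spread, 12 adjusted over the list alone, camera, adjusted p = 0.000321 and, with an estimated correlation, adjusted p = 0.214). Among them were Pcyt2 (-1.85 ± 0.29) and Ahcy (-1.47 ± 0.28), while Pemt had -0.50 ± 0.21 and Bhmt -0.84 ± 0.36. Fatty acid oxidation genes did not pass as a list (1 up and 4 down of 21, 2 and 0 by own spread, the main numbers also adjusted over the list alone, camera, adjusted p = 0.714), with a median of -0.10 and a mean of 0.12.

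Lists of hepatocyte genes were tested in the same preparations, in which Kupffer markers rose by a median of 6.94. Growth hormone and male-biased genes had 10 of 14 down (8 by own spread, 10 adjusted over the list alone, camera, adjusted p = 5.18e-08), with a median of -2.89. Among them were Elovl3 (-8.43 ± 1.18) and Cyp4a12a (-6.14 ± 0.59). Hepatocyte transcription factors had 8 of 16 down but 1 by own spread (13 adjusted over the list alone, camera, adjusted p = 2.31e-05 and, with an estimated correlation, adjusted p = 0.189). Lower ones included Mlxipl (-3.25 ± 0.33), Cebpa (-2.12 ± 0.42), Thrb (-2.29 ± 0.50) and Hnf4a (-1.72 ± 0.46). By own spread Cebpa, Thrb and Hnf4a did not pass, with adjusted p = 0.0640, 0.0703 and 0.164. Hepatocyte function genes had 7 of 21 down (4 by own spread, 10 adjusted over the list alone, camera, adjusted p = 4.39e-05 and, with an estimated correlation, adjusted p = 0.0586). Among them were Agxt (-3.11 ± 0.39) and F7 (-2.18 ± 0.34), and Alb had -0.01 ± 0.16. Alb lay at 19.82 on CSAA, at the top of the array values, where a change can hardly show. Centring on the 3 less bright hepatocyte function genes turned the medians of 14 of 35 lists to the other sign. This is a scaling chosen after the data were seen. Those that turned included transcription factors (from -1.64 to 0.54), hepatocyte function (from -0.77 to 1.41) and lipogenesis (from -1.79 to 0.40). Bile acids (from -0.999 to 1.18) and one-carbon metabolism (from -0.86 to 1.32) turned too, but not cholesterol synthesis or the male-biased genes. Cholesterol synthesis kept its direction but moved from -3.40 to -1.22, with 13 genes passing downward in place of 19. Cytochrome P450 and conjugation genes had 4 up and 9 down of 20 (3 and 5 by own spread, 5 and 10 adjusted over the list alone, camera, adjusted p = 0.158). Of these Cyp2a5 (6.14 ± 0.68) was higher and Cyp2j5 (-1.96 ± 0.18) lower. Periportal genes had 1 up and 5 down of 10 (1 and 3 by own spread, 1 and 7 adjusted over the list alone, camera, adjusted p = 0.036 and, with an estimated correlation, adjusted p = 0.331). Lower were Hal (-3.36 ± 0.48) and Cyp2f2 (-2.20 ± 0.38). Oxidative phosphorylation genes had 2 of 17 down (1 by own spread, 2 adjusted over the list alone, camera, adjusted p = 0.0485 and, with an estimated correlation, adjusted p = 0.455). Sugar metabolism (3 up and 6 down of 19, 2 and 2 by own spread), the unfolded protein response (1 up and 5 down of 22, 1 and 1 by own spread), the circadian clock (1 of 16 down, 0 by own spread) and pericentral genes (1 up and 1 down of 12, 0 and 0 by own spread) did not pass as lists, with adjusted p = 0.181, 0.256, 0.274 and 0.745. Adjusted over the list alone, sugar metabolism had 4 up and 8 down, the unfolded protein response 2 and 7, and the other lists the same numbers as over all genes.

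Over all 22206 probe sets tested in primary hepatocytes, 4158 passed, 2439 higher and 1719 lower, of which 2114 and 1097 differed by a log2 value of at least 1. With the spread taken from the 6 hepatocyte arrays alone 1883 passed, 1450 higher and 433 lower, and 1874 of these were among the 4158. Of 67 genes given here as changed in hepatocytes, 36 had 1 group and 1 had both groups wholly under the 95th percentile of the intron controls. Transcription factors passing downward were 5 without CDAA replicate 2, CDAA replicate 3 or CSAA replicate 1, and lipogenic genes 7 without CSAA replicate 2. Without CDAA replicate 1, 12 transcription factors and 15 lipogenic, 7 fatty acid oxidation, 4 cholesterol export, 4 oxidative stress and 10 unfolded protein response genes passed downward and 7 T and NK cell markers upward. The unfolded protein response had 1 without CSAA replicate 1 and 2 without CDAA replicate 3. On simulated values in which each tissue had its own spread, 17.2% of the hepatocyte calls of the shared-spread fit were false with 4000 changed genes and 52.5% with 200 genes, against 3.95% and 3.51% with the own spread. The groups did not overlap in 5904 probe sets, 26.6% of those tested, against 10% by chance. By camera, 27 of 35 lists shifted, 18 up and 9 down, of which 11 held with an estimated correlation. Those 11 had adjusted p of 0.0016 to 0.0352 by camera with the estimated correlation, far above their preset values. Array weights gave 6806 genes, and centring on the 3 less bright hepatocyte function genes gave 21336, moving the median of all genes from -0.13 to 2.05. The higher share was 58.7%, against 43.5% after joint quantile normalization, 39.9% after centring on array medians and 88.7% after centring on all hepatocyte function genes.

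The third comparison asked where the diet effect differed between the tissues, as the effect in total liver minus the effect in hepatocytes. The tissues' values look normalized as 2 separate sets, so this difference assumes that a log2 step means the same in both. Markers of Kupffer, endothelial and stellate cells rose less in total liver than in the hepatocyte preparations, by -7.30 ± 0.81 (bound -5.12) for the Kupffer marker Clec4f and -7.03 ± 0.54 (bound -6.10) for Cd5l. Hepatocyte genes such as Mlxipl (2.08 ± 0.44), Cyp17a1 (3.47 ± 0.85, bound 1.58) and F12 (1.98 ± 0.49) and the transporter gene Abcc4 (2.43 ± 0.53, no bound) had higher differences, as did Aox3 (2.40 ± 0.60); further lower differences were those of Wfdc17 (-6.94 ± 0.92, bound -5.44), Lyz2 (-6.67 ± 0.71, bound -5.51) and C1qb (-6.51 ± 0.76, bound -4.07). With a spread estimated per tissue, Mlxipl, F12, Abcc4, Aox3 and Cyp2j5 did not pass, with adjusted p = 0.0666, 0.149, 0.0542, 0.169 and 0.0507.

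Of the 12 Kupffer cell markers, 11 had a lower effect in total liver (12 adjusted over the list alone, camera, adjusted p = 1.45e-31 and, with an estimated correlation, adjusted p = 0.00733), with a median difference of -5.35. The same held for 14 of 17 sinusoidal endothelial markers (15 adjusted over the list alone, camera, adjusted p = 9.02e-30). Among them were Fcgr2b (-4.66 ± 0.48) and Clec4g (-5.66 ± 0.77). It also held for 9 of 12 stellate cell markers (11 adjusted over the list alone, camera, adjusted p = 5.04e-20). Among them were Vipr1 (-3.57 ± 0.38, no bound) and Sod3 (-4.95 ± 0.59, bound -2.97). In CSAA hepatocytes 12 of 12 Kupffer, 12 of 17 endothelial and 11 of 12 stellate markers lay wholly under the percentile of the intron controls, so the sizes of the list medians here and in hepatocytes rest partly on values not above background. Cytokine and chemokine genes had 11 of 24 lower (18 adjusted over the list alone, camera, adjusted p = 3.24e-23). Among them were Ccl3 (-4.92 ± 0.38, no bound) and Il1a (-5.21 ± 0.47, no bound). MHC class II was lower (7 of 8, 7 adjusted over the list alone, camera, adjusted p = 2.11e-13 and, with an estimated correlation, adjusted p = 0.0518). So were recruited macrophage markers (5 of 16, 11 adjusted over the list alone, camera, adjusted p = 4.71e-09 and, with an estimated correlation, adjusted p = 0.129). Extracellular matrix genes were lower as well (5 of 23, 9 adjusted over the list alone, camera, adjusted p = 1.6e-08 and, with an estimated correlation, adjusted p = 0.129). Immediate early genes had 3 of 17 lower (6 adjusted over the list alone, camera, adjusted p = 4.52e-05 and, with an estimated correlation, adjusted p = 0.359). These were the heat shock genes Hspa1a (-4.99 ± 0.64, no bound) and Hspa1b (-5.27 ± 0.81, no bound), which are near-identical paralogues, and Dusp1 (-2.52 ± 0.57), which had adjusted p = 0.0545 with a spread estimated per tissue. B cell markers, 8 of 8 of them wholly under the intron control percentile in each group, were lower as a list with 0 of 8 passing (camera, adjusted p = 0.0206 and, with an estimated correlation, adjusted p = 0.188). Proliferation genes (1 of 20, camera, adjusted p = 0.000245 and, with an estimated correlation, adjusted p = 0.0518) and lysosomal genes (2 of 15, camera, adjusted p = 0.00016 and, with an estimated correlation, adjusted p = 0.0944) were also lower as lists. Members lower adjusted over the list alone were 1, 2 and 5 in these 3.

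For genes of cholesterol synthesis no member passed by limma over all genes or adjusted over the list alone, and the list median was 0.54 (camera, adjusted p = 0.0126 and, with an estimated correlation, adjusted p = 0.359), with -0.03 ± 0.47 (no bound) for Sqle. That median was 0.036 after joint quantile normalization and 0.154 with array weights. Male-biased genes also had no member past the threshold (camera, adjusted p = 0.347), and their median of 0.32 turned to -0.26 after joint quantile normalization. Higher as lists were hepatocyte function (median 0.38, camera, adjusted p = 0.000192 and, with an estimated correlation, adjusted p = 0.115) and lipogenesis (0.91, camera, adjusted p = 2.37e-05 and, with an estimated correlation, adjusted p = 0.359). So were one-carbon metabolism (0.60, camera, adjusted p = 0.000928 and, with an estimated correlation, adjusted p = 0.359) and hepatocyte transcription factors (0.66, camera, adjusted p = 0.0019 and, with an estimated correlation, adjusted p = 0.359). In those 4 lists Mlxipl alone passed over all genes or adjusted over the list alone, but this changed in both directions under alternatives. Without hepatocyte CSAA replicate 1, CSAA replicate 2 or CDAA replicate 2, 0 transcription factors and 0 lipogenic genes passed upward. Without hepatocyte CSAA replicate 3, 2 lipogenic genes did. Without hepatocyte CDAA replicate 1, 6 hepatocyte function, 8 lipogenic and 8 one-carbon genes, 6 transcription factors and 2 cholesterol synthesis genes passed upward, and with array weights 6, 10, 5, 6 and 1. The same array left out gave 6 bile acid, 4 unfolded protein response, 4 cytochrome P450 and 3 periportal genes, and 9 recruited macrophage, 9 matrix, 5 proliferation and 5 lysosomal genes downward. Recruited macrophage markers passing downward were 2 without hepatocyte CDAA replicate 2, hepatocyte CSAA replicate 1 or 2, total liver CDAA replicate 4 or total liver CSAA replicate 1. Bile acid genes (0.39, camera, adjusted p = 0.0061 and, with an estimated correlation, adjusted p = 0.359) and fatty acid oxidation (0.46, camera, adjusted p = 0.00711 and, with an estimated correlation, adjusted p = 0.521) were higher too. The unfolded protein response (0.52, camera, adjusted p = 0.0124 and, with an estimated correlation, adjusted p = 0.521) and cytochrome P450 (0.38, camera, adjusted p = 0.0193 and, with an estimated correlation, adjusted p = 0.369) followed. Periportal genes were the last of the higher lists (1.15, camera, adjusted p = 0.00197 and, with an estimated correlation, adjusted p = 0.277). In them 1 gene passed over all genes, Cyp2j5 (1.15 ± 0.24), and 4 cytochrome P450 and 5 periportal genes rose adjusted over the list alone, with 1 periportal gene falling. Centring on the 3 less bright hepatocyte function genes turned the medians of 20 of 35 lists to the other sign, including cholesterol synthesis (-0.79), the male-biased genes (-1.004) and all the other lists just named as higher.

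**Figure D2:**
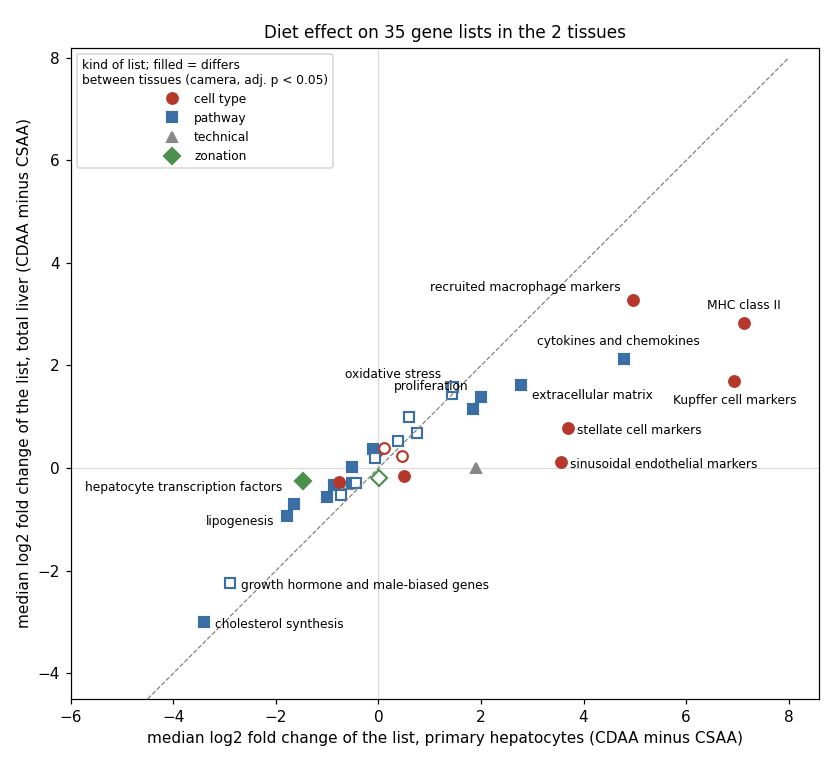
Each point is 1 of 35 gene lists: its median log2 fold change, CDAA minus CSAA, in primary hepatocytes (horizontal) and total liver (vertical), with the dashed line where both are equal. Filled points differ between tissues by camera at the preset correlation. Kupffer markers lie at 6.94 and 1.69 and cholesterol synthesis at -3.40 and -3.001, while hepatocyte transcription factors and lipogenesis change sign in hepatocytes when arrays are centred on the 3 less bright hepatocyte function genes.

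Over all probe sets 570 differed between tissues, 47 with a higher and 523 with a lower effect in total liver, all of them by a log2 value of at least 1. With a spread estimated per tissue, chosen after the data were seen, 396 passed (16 higher and 380 lower), 392 of them among the 570. Of 48 named genes past the threshold, 10 had no group wholly under that percentile, 14 keep a bound and 24, Mmp12 among them, have none. By camera 21 of 35 lists differed, 10 up and 11 down, of which 4 held with an estimated correlation, and fry gave 11. Those 4 had adjusted p of 0.0073 to 0.0132 by camera with the estimated correlation, far above their preset values. The count was 2725 with array weights (1035 higher and 1690 lower), 2265 without hepatocyte CDAA replicate 1 (1025 higher and 1240 lower) and 4145 with centring on the 3 less bright hepatocyte function genes. The 47 higher genes were 16 without hepatocyte CSAA replicate 1, 16 without hepatocyte CDAA replicate 2, 20 without hepatocyte CSAA replicate 2 and 20 without total liver CSAA replicate 1. Over the other total liver arrays left out they were 24 to 32.

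The last comparison asked how far the diet effects in the tissues overlapped. Cholesterol synthesis genes, Hsd3b5, Mmp12 and Gpnmb changed the same way in both. In all, 1609 probe sets passed in the same direction in both tissues, 1158 up and 451 down, against 164.1 and 60.8 expected if the calls were independent, and 2 passed in opposite directions. The calls shared 1 spread per probe set and so were not independent, and the expected numbers are only a rough guide. With each tissue's own spread 1518 passed in the same direction, 1182 up and 336 down. Pearson's r of the log2 fold changes was 0.777 across genes, which are not independent replicates, so no p is given. The overlap was 2863 with array weights and 5383 with centring on the 3 less bright hepatocyte function genes. The higher share of the shared genes was 72.0%, against 58.9% after joint quantile normalization, 53.7% after centring on array medians and 87.3% after centring on all hepatocyte function genes.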

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

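Tests chosen only after the result was seen were the count of markers of other cells, the endothelial median in total liver, the change needed there for a rise within hepatocytes, the level-matched hepatocyte genes, both centrings on hepatocyte function genes, the bound on background, and the stricter reading of the female-biased list.

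Markers of other liver cells rose more in the CDAA hepatocyte preparations than in CDAA total liver. The tables argue against separate normalization of the tissues as the whole source: after joint quantile normalization the Kupffer markers still differed by a median of -4.74. They also argue against a rise of endothelial cells in the liver itself, whose markers had a median of 0.12 in total liver, but do not exclude it. On each diet 8 of 17 of these markers lay wholly under the intron control percentile, where a small rise can be missed. Lying there did not prevent a call, since 15 of 20 proliferation genes passed upward in total liver with 19 of 20 under it. The list mean was -0.33 in CDAA replicate 1 against 0.30 to 0.49 in the other CDAA arrays. Centring on the 3 less bright hepatocyte function genes gave a median of 0.97 with 8 up. A rise within hepatocytes of the animal would have to show in total liver too. If hepatocytes gave 0.5 of its RNA, the change seen there minus the change needed had a median of -0.45 over the 41 markers (quartiles -0.90 and 0.001), and -0.95 after joint quantile normalization (-1.55 and -0.52). This goes against such a rise but does not exclude it, since the deposited values reach 0 at the upper quartile, the share of 0.5 is assumed, and levels are set side by side between tissues that look separately normalized. A rise during isolation would not show in total liver and was not tested, and other cells carried into the CDAA preparations stay open too. That 39 of 41 markers of Kupffer, endothelial and stellate cells passed upward only restates the pattern and supports none of these; the labels name no step after perfusion that would remove other cells.

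Hepatocyte transcription factors had a median of -1.64 in the hepatocyte preparations and -0.69 in total liver. Dilution by RNA of other cells could lower them, and this cannot be told apart from a fall within hepatocytes. Centring on the 3 less bright hepatocyte function genes gave a median of 0.54. This met the condition set for dilution but cannot decide. It shifts every gene by the fall of 3 genes chosen after the data were seen. It also took the hepatocyte function median to 1.41, with 15 of 21 genes passing upward. Dilution alone would leave that median near 0 only if the brighter genes could fall as far as those 3. The 1.41 therefore does not decide either. Centring on all 21, added afterwards, gave -1.20 with 4 genes still down, but decides nothing: the 21 have a median level of 17.98 in CSAA hepatocytes, the brightest at the top value of the arrays (19.82), where probe sets can hardly fall on dilution, and the quartiles of -1.55 and -0.54 span the bound of -1 set beforehand. The difference between tissues had adjusted p = 0.0019 by camera and adjusted p = 0.359 with an estimated correlation, so a stronger fall in hepatocytes is itself uncertain.

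Male-biased genes fell in both tissues, in total liver by a median of -2.24. The tables argue against fewer hepatocytes as the whole cause: 54 other hepatocyte genes no brighter than the median male-biased gene had a median of -0.48 (quartiles -0.84 and -0.09). A shift toward the female liver pattern may take part: the 18 measured female-biased genes had a median of 0.60 in total liver (limma's camera, adjusted p = 0.0165 as the only list tested), which met the condition set beforehand. It stays open because the estimated correlation gave adjusted p = 0.110, because in hepatocytes the list had a median of 0.26 and did not pass (p = 0.0525, and 0.187 with an estimated correlation), and because Cyp2a4, Cyp2b9, Cyp3a41a, Cyp3a41b and Cyp3a44 rose while Cyp2c40 (-3.81 ± 0.48) and Cyp2c69 (-2.35 ± 0.35) fell. Whether the probe sets of Cyp2a4, Cyp3a41a, Cyp3a41b and Cyp3a44 tell close copies apart was not checked, so their rises need not be separate. Growth hormone was not measured.

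Other splits of the arrays by diet bear on each count. In total liver 1 of 35 splits, the real one, gave as many as 2279 genes and the highest other gave 0. With 35 splits 1 of 35 is the smallest share possible. The other splits mix the diets, which adds the diet effect to their spread and lowers their counts. The count of genes thus argues against chance there but does not exclude it. For lists 6 of 35 splits gave as many as 22, the highest other 27, so chance cannot be excluded. In hepatocytes 3 arrays against 3 make 10 splits, too few for a share under 0.05: the real split alone (1 split) gave 4158 genes, the highest other 2382, and 27 lists, the highest other 21. For the difference between tissues 12 of 100 splits gave as many as 570 genes, the highest other 2904, and 27 of 100 gave as many as 21 lists, the highest other 30, so by these splits chance cannot be excluded. But 10 of the 11 other splits with as many genes, and 10 of the 26 with as many lists, kept the diets fully parted in either tissue. Such splits carry the diet effect itself, which points to a structure of the samples, and they are no clean measure of chance.

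Single arrays stood far from the other 3 of their group in 12 of 214 groups of 4 tested. With 214 groups tested some would be flagged by chance. That number was not computed, so the 12 cases need not be real outliers. In total liver on CSAA these were, as log2 values with the range of the other arrays, Cyp2a5 13.84 in replicate 2 (12.52 to 12.65), Hsd17b13 17.20 in replicate 1 (17.46 to 17.50), Idi1 14.08 in replicate 2 (14.997 to 15.18), Ncr1 5.18 in replicate 4 (4.38 to 4.42), Onecut1 10.25 in replicate 2 (14.34 to 14.93), Il1a 8.28 in replicate 3 (7.84 to 7.86). In total liver on CDAA they were Cyp4a12b 8.21 in replicate 1 (10.65 to 11.002), G6pc 16.28 in replicate 2 (14.73 to 14.95), Lilr4b 11.76 in replicate 1 (10.87 to 10.94), Pdgfrb 10.42 in replicate 1 (8.75 to 8.98), S100a8 7.88 in replicate 1 (5.61 to 5.73), Vcam1 11.96 in replicate 1 (11.11 to 11.22). Of these 6, 5 were in replicate 1, which also stood beyond the other 3 arrays in 9 list means, by more than 0.5 and by more than their range. Against the CSAA mean, recruited macrophage markers were 4.46 in CDAA replicate 1 against 3.33 to 3.54 in the other CDAA arrays. In the same order the values were 2.68 against 1.56 to 1.80 for matrix genes, 1.28 against 0.48 to 0.60 for neutrophil, 1.07 against 0.02 to 0.36 for cholangiocyte and -0.33 against 0.30 to 0.49 for endothelial markers, -4.18 against -3.09 to -2.79 for male-biased genes, 2.68 against 1.68 to 1.97 for cytokines, 3.10 against 1.90 to 2.33 for MHC class II and 1.16 against 0.15 to 0.66 for immediate early genes. By this rule, chosen after the values were seen, 3 more list means had an array apart in total liver: CDAA replicate 2 in fatty acid oxidation, CDAA replicate 3 in the unfolded protein response and CSAA replicate 2 in Kupffer markers.

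The test of the difference between tissues passed for 48 of 131 genes named, against 570 of all 22206 probe sets tested. Part of the 131 were named for this very difference, so the 48 are no measure of how common it is. The effect in total liver was lower (log2 difference ± SE) for C1qa -5.29 ± 0.57 (bound -4.38), C1qb -6.51 ± 0.76 (bound -4.07), Ccl3 -4.92 ± 0.38 (no bound), Cd36 -4.34 ± 0.53 (no bound), Cd5l -7.03 ± 0.54 (bound -6.10), Cdh5 -3.99 ± 0.55 (bound -2.15), Clec4f -7.30 ± 0.81 (bound -5.12). It was also lower for Clec4g -5.66 ± 0.77, Col3a1 -2.74 ± 0.50 (no bound), Csf1r -4.83 ± 0.43 (bound -2.32), Ctsb -1.38 ± 0.27, Cxcl2 -4.75 ± 0.49 (no bound), Dcn -5.99 ± 0.78, Des -1.87 ± 0.40 (no bound). Others were Dusp1 -2.52 ± 0.57, Fabp4 -3.76 ± 0.80 (no bound), Fabp7 -5.70 ± 0.58 (no bound), Fcgr2b -4.66 ± 0.48, H2-Aa -4.88 ± 0.76 (bound -3.90), H2-Ab1 -5.29 ± 0.78 (no bound), Hexa -1.77 ± 0.35. To these add Hilpda -2.43 ± 0.60 (no bound), Hmox1 -3.28 ± 0.50 (no bound), Hspa1a -4.99 ± 0.64 (no bound), Hspa1b -5.27 ± 0.81 (no bound), Il1a -5.21 ± 0.47 (no bound), Lcn2 -3.98 ± 0.91 (bound -1.99), Lilr4b -3.06 ± 0.52 (no bound). Further ones were Lilrb4a -6.03 ± 0.63 (bound -2.92), Lyve1 -3.61 ± 0.52 (no bound), Lyz2 -6.67 ± 0.71 (bound -5.51), Mmp12 -4.25 ± 0.58 (no bound), Mylip -3.82 ± 0.62 (no bound), Pkm -3.35 ± 0.40 (no bound), Rgs1 -6.39 ± 1.07 (no bound). The last were Sod3 -4.95 ± 0.59 (bound -2.97), Sparc -6.38 ± 0.56 (bound -5.79), Trem2 -3.71 ± 0.85 (no bound), Vcam1 -5.01 ± 0.42 (no bound), Vipr1 -3.57 ± 0.38 (no bound), Wfdc17 -6.94 ± 0.92 (bound -5.44). It was higher for Abcc4 2.43 ± 0.53 (no bound), Aox3 2.40 ± 0.60, Cyp17a1 3.47 ± 0.85 (bound 1.58), Cyp2j5 1.15 ± 0.24, F12 1.98 ± 0.49, Mlxipl 2.08 ± 0.44, Mx1 1.43 ± 0.32 (no bound). With a spread estimated per tissue Abcc4, Aox3, Cyp2j5, F12 and Mlxipl did not pass, nor did Dusp1 among the lower ones. Not all of the 48 were looked at singly under that spread. Mx1 lay wholly under the intron control percentile in all 4 groups. A bound is given where a group lay wholly under the 95th percentile of the intron controls, and "no bound" stands where none is left, for 24 of these 48 genes.

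Outside the tested probe sets, the median of the 31 AFFX control probe sets was 0.019 higher on CDAA in hepatocytes, with the lowest CDAA array at 5.0393 and the highest CSAA array at 5.0375. The median of the 63 ERCC control probe sets was 0.229 lower on CDAA in total liver, with the highest CDAA array at 3.9742 and the lowest CSAA array at 4.0222, and that of the 5222 intron control probe sets 0.298 lower in hepatocytes, with 4.0146 and 4.0677.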

How the results depend on the processing

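Alternatives chosen only after the result was seen were both centrings on hepatocyte function genes and the spread estimated per tissue. The totals of genes and lists stayed within 1.5 times under trend and robust moderation, the filter on dim probe sets, joint quantile normalization, centring on array medians, the replicate block and the mean over a gene's probe sets. Their parts did not all do so: centring on array medians moved lower genes from 1719 to 3244 in hepatocytes, 785 to 1650 in total liver and 451 to 858 in the overlap, joint quantile normalization moved lower genes in hepatocytes to 3068 and higher genes of the difference from 47 to 73, and the filter moved lower lists in total liver from 5 to 8. The fit on the compared groups alone gave 1883 genes in hepatocytes and 4613 in total liver, as each tissue's own spread replaced the shared one. Array weights gave 6806, 4992 and 2725 genes in hepatocytes, total liver and for the difference, and an overlap of 2863; the cause was not tested. Centring on the 3 less bright hepatocyte function genes gave 21336, 5458, 4145 and 5383, since it moves the median of all hepatocyte log2 fold changes from -0.13 to 2.05. An estimated correlation left 11, 9 and 4 lists, and fry left 11 for the difference; the cause was not tested. Without single arrays the counts ranged from 3039 to 5811 genes in hepatocytes, 1510 (without total liver CDAA replicate 1) to 1911 in total liver, 396 to 2265 (without hepatocyte CDAA replicate 1, with all 570 remaining) for the difference, 1199 to 2019 for the overlap and 0.717 to 0.8002 for r, where fewer arrays were left. The numbers of lists ranged from 23 to 27 in hepatocytes, 20 to 26 in total liver and 15 to 23 for the difference.

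Of 3350 values of named genes under alternatives, 3122 kept direction and side of the threshold, 156 no longer passed, 22 newly passed and 50 changed sign; the cause of the changes of sign was not tested. Changes of sign, as log2 fold changes, were under joint quantile normalization in hepatocytes Alb 0.063, Scd1 0.032, in total liver Alb 0.00, for the difference Sqle 0.38; under centring on array medians in total liver Plin2 -0.11; and under array weights in hepatocytes Alb 0.022, Socs2 -0.19, in total liver Plin2 -0.046. Centring on the 3 less bright hepatocyte function genes, of which F7 is 1, gave in hepatocytes Ahcy 0.71, Alb 2.18, Bhmt 1.34, Cebpa 0.056, Cyp2j5 0.23, F7 0.00, Hnf4a 0.46, Pcyt2 0.33, Pemt 1.68, Plin2 1.76, Scd1 2.10, in total liver Acaa2 0.19, Alb 0.85, Bhmt 0.73, Cd4 0.047, Hnf4a 0.33, Pemt 0.54, for the difference Cyp2j5 -0.18. Centring on all of them gave in hepatocytes Alb 0.43, Plin2 0.019, Scd1 0.36, in total liver Alb 0.19, Bhmt 0.061. Without single arrays the ranges of those that changed sign were Alb in hepatocytes -0.055 to 0.068, Alb in total liver -0.021 to 0.023, Plin2 in total liver -0.13 to 0.13, Scd1 in hepatocytes -0.90 to 0.37, Socs2 in hepatocytes -0.45 to 1.03, Sqle for the difference -0.32 to 0.23. Of the genes named, those that changed sign while past the threshold as deposited were Ahcy, Cebpa, Cyp2j5, F7, Hnf4a and Pcyt2 in hepatocytes and Acaa2 and Cd4 in total liver and Cyp2j5 for the difference, under the centring on 3 genes alone. Among alternatives, total liver against hepatocytes on CSAA was not run. Signal over background limits dim genes: no detection calls were used here.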

Other observations

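The gene of this part was picked after its values were seen, without a new test. The growth hormone target Socs2 had 0.34 ± 0.82 in hepatocytes and -2.01 ± 0.71 in total liver, neither past the threshold, with a difference of -2.35 ± 1.08 that did not pass either; with the spread from the total liver arrays alone Socs2 passed there, with adjusted p = 0.0296.

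The 3 CDAA hepatocyte arrays were unlike each other. Replicate 1 stood 5.67 above the CSAA mean for Kupffer cell markers, against 7.28 and 6.90 in replicates 2 and 3, and 3.71 above it for immediate early genes, against 1.80 and 1.15. Intron control probe sets had array medians of 3.71 to 4.01 in the CDAA hepatocyte arrays, 4.07 to 4.21 in the CSAA hepatocyte arrays and 5.97 to 6.21 in total liver. No pair of arrays was a duplicate: the smallest mean absolute difference between 2 arrays was 0.274.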
